A study of Homo sapiens with 16 samples.

How the data were processed

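The samples were Caco-2 cells, grown in 6-well plates, kept without serum for 16 h and treated for 24 h, and their transcripts were measured on two-colour Agilent arrays of 45015 spots. Per the labels, 16 arrays carried GED at 1 mM (named AGO in the labels) or 30 mM, pioglitazone at 1 µM, or 5-ASA at 30 mM, with 4 arrays each, 2 with the treated RNA in Cy5 and 2 in Cy3. The other channel held pooled control RNA, from 3 pools: 1 for GED 1 mM (members not given in the sources used here), 1 of 2 members shared by GED 30 mM and 5-ASA, and 1 of 4 members for pioglitazone. The study text states 6 replicates per treatment, and 4 arrays per treatment were in hand. Whether replicates were separate cultures or days, and which pool held vehicle, is not given in the sources used here, so p-values measure the spread between these samples. GED 1 mM had a slide and a scan day of its own (4 arrays), and the other 12 arrays lay on 3 slides that mixed treatments and shared a scan day.

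Per the file headers, the scanner files hold intensity values for each spot and channel (mean spot brightness and median local background), processed intensity values, and a log10 ratio of red over green. They also hold spot classes and quality marks, values of other kinds per the file headers. The deposited value table is the log10 ratio with the sign turned so that treated RNA is on top, and differed from the scanner files by at most 4.97e-06. Image reading and the log10 ratios were made by the authors with Agilent Feature Extraction, and how RNA was pooled and labelled beyond this is not given in the sources used here.

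Mean spot intensities were background-corrected with normexp (offset 50) and loess-normalized within each array in limma 3.58.1 under R 4.3.3, with data.table (version 1.17.8) and jsonlite (version 2.0.0) for reading. Spots marked by the scanner for a non-uniform local background took the array's median background in that channel, a choice made after the spread of the arrays was seen, because a few extreme backgrounds had upset the correction on 3 arrays. Control spots (1639) were dropped. Of 41000 probes, 30667 had a gene symbol: 27210 by accession, 2364 by current symbol, 468 by synonym and 625 by the name in the file, with 10333 left without. A probe was kept if it was well above background in the treated or the control channel on at least 3 of the 4 arrays of a treatment, which left 28462 probes, and the probe with the highest mean intensity stood for each gene, which gave 14515 genes. Between 58.5% and 85.0% of probes per array and channel were well above background, no spot was saturated, and 33 genes lacked a spot on some array.

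Log2 ratios of treated over pool were fitted in limma over all 16 arrays with 1 mean per treatment and a dye effect (residual degrees of freedom 11, prior 6.24), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. A treatment was tested as its ratio against 0, and 2 treatments as the difference of their ratios. A dye effect was called for 6348 genes. A pool is 1 control sample, so the spread between control wells is not in these tests. Gene lists (23 lists, 476 members, 415 measured, 6 genes in over 1 list) were written before the data were examined and tested with camera at a preset correlation of 0.01 and at an estimated one, adjusted over 23 lists. Counts adjusted over the list alone correct the p-values of that list's members by themselves. A standard error beside a list median is taken over the list's genes, which are not independent replicates. It leaves out the spread between arrays, wells and pools. Of 115 tests in the 4 treatments and the 30 mM difference, 42 lists were called at the preset correlation and 11 at the estimated one.

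Genes are named by rule. In each treatment and in the 30 mM difference these are the 7 largest rises and 7 largest falls among called genes with the same sign on every array, passing over names that are accessions, clones or open reading frames. For the 30 mM difference, the same sign on every array means that every array of 1 treatment lies above every array of the other. From each called list the 2 members with the smallest p are named, in every treatment LCT, PPARG, PPARA, PPARD, RXRA, ANGPTL4, PDK4, PLIN2 and FABP1, and, of genes changed the same way by all 4 treatments, the 10 with the largest mean absolute log2 ratio. A few genes that the rule picks are left out of the text. A gene not well above background on 1 side is given as at least its fold.

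Simulations of unchanged groups, 20 draws, gave control wells the spread of the arrays and averaged 2, 4 and 2 wells for the shared, pioglitazone and GED 1 mM pools, the last an assumption. The pipeline was also tested on simulated data with changes of known size. Alternatives tried were array weights, no background correction, the scanner's processed log ratios, the deposited table, scaling between arrays, median centring, no dye term, looser and stricter filters, every probe on its own, the mean over probes, a replicate block, fits of the compared arrays alone, slide as a random block, and leaving out each array. Added later were the local background kept as scanned, slide as a fixed block, a dye effect per slide, standard errors widened for control wells, every alternative for the pairs with pioglitazone and for 5-ASA minus GED 1 mM, and leaving out each array for the gene lists. All 16 value columns of the deposited table were matched to arrays, and probes without a gene symbol were left out of gene counts.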

Results

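The experiment set 4 treatments of human intestinal epithelial cells side by side, to compare agonists of PPARγ, a nuclear receptor that switches on genes of lipid handling. Caco-2, a colon carcinoma line that takes on features of small intestinal enterocytes in culture, was kept without serum for 16 h and then treated for 24 h. The treatments were GED (a compound named here by its code alone) at 1 mM and at 30 mM, 5-ASA (5-aminosalicylic acid, an anti-inflammatory drug) at 30 mM, and pioglitazone (a thiazolidinedione agonist of PPARγ) at 1 µM. Each treatment had 4 two-colour arrays, 2 with the treated RNA in Cy5 and 2 with it in Cy3, set against pooled control RNA. GED 30 mM and 5-ASA shared a control pool, and GED 1 mM and pioglitazone each had a pool of their own. Between 58.5% and 85.0% of the 41000 probes were well above background per array and channel, no spot was saturated, and 14515 genes were tested. The standard deviation of the log2 ratios on 1 array was 0.137 to 0.175 for GED 1 mM, 0.192 to 0.233 for pioglitazone, 0.308 to 0.338 for GED 30 mM and 0.525 to 0.556 for 5-ASA. Because every array sets treated wells against 1 pool, the tests leave out the spread between control wells, and the number of arrays limits the precision.

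Pioglitazone asked what a known PPARγ agonist does to these cells. LCT, which encodes the brush border enzyme lactase, rose 9.38-fold (log2 3.23, SE 0.119, n = 4 arrays, adjusted p = 1.24e-12), read by a probe on chromosome 2 from 136545887 to 136545946 in hg19. CREB3L3, a transcription factor of lipid metabolism, rose 6.12-fold (log2 2.61, SE 0.0735), and PLIN2, a coat protein of lipid droplets, rose 4.98-fold (log2 2.32, SE 0.0621). GUCA2A, the gut peptide guanylin, rose 4.66-fold, SLC51A, a subunit of the basolateral bile acid exporter, 4.55-fold, GPA33, a gut surface antigen, 3.64-fold and the kinase SGK2 3.58-fold. Weaker further probes gave 0.81 for CREB3L3, 0.37 for GPA33, -0.40 for RASD1 and, for genes named below, -0.10 for ASCL2, -0.09 for UHRF1, -0.21 for MT1X, 0.08 for CA12 and 0.10 for ALDOA. The falls were smaller: the metallothionein MT2A had a log2 ratio of -1.54 (SE 0.112), the transcription factor SOX2 -1.44, ENC1 -1.13, the sodium-potassium-chloride transporter SLC12A2 -1.12, RASD1 -0.99, RAMP1 -0.95 and SI, the brush border enzyme sucrase-isomaltase, -0.95. In limma's test 5512 genes changed, 2724 higher and 2788 lower, of which 71 rose and 4 fell at least 2-fold. With each array centred on its median 34.3% of the called genes were higher, against 49.4%. The count was 2900 with the local backgrounds kept as scanned and 3122 with control wells given the spread of the arrays. In 20 simulations of unchanged wells whose control wells vary like the arrays, a median of 86 genes were called. Against the control pool of the 30 mM treatments 4818 of the 5512 called genes (87.4%) kept their sign. Among the falls named, MT2A had only -0.60 and SI -0.48 against that pool. The others had -1.40 (SOX2), -1.12 (ENC1), -1.32 (SLC12A2), -0.98 (RASD1) and -1.09 (RAMP1).

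Of 32 PPAR targets measured, 27 rose and 1 fell under pioglitazone (28 and 1 adjusted over the list alone), with a median log2 ratio of 0.61 (camera adjusted p = 1.55e-21, and adjusted p = 0.00603 with an estimated correlation). Beside PLIN2 and CREB3L3, the fatty acid binding protein FABP1 rose 3.07-fold (log2 1.62, SE 0.0735). PDK4, a kinase that restrains glucose oxidation, was not well above background in the control pool and rose at least 1.28-fold, and the lipase inhibitor ANGPTL4 rose by 0.27 on the log2 scale. Among the receptors, PPARG itself fell by 0.35 (SE 0.0387, adjusted p = 1.36e-06), PPARA rose by 0.17 and PPARD by 0.14, and RXRA, their partner receptor, had -0.04 (adjusted p = 0.468, with 1 of its 3 probes of the same sign). The PPARA call ended without replicate 1 (0.15, adjusted p = 0.0929) or replicate 3 (0.14, adjusted p = 0.108), and the PPARD call ended without replicate 1 (0.11, adjusted p = 0.0645). The calls of PPARA and PPARD also ended with median centring, with the backgrounds kept or with control wells given a spread, and those of PPARG and SMOC2 with the backgrounds kept. Wnt targets fell, 13 of 19 lower and 0 higher (14 adjusted over the list alone). The list median was -0.37 (camera adjusted p = 2.81e-08, adjusted p = 0.00104 with an estimated correlation). Examples were the transcription factors SP5 (-0.75, with 1 of its 3 probes opposite) and ASCL2 (-0.60). Stem cell markers fell too, 6 of 10 lower and 0 higher (6 adjusted over the list alone). The genes had a median of -0.28 (camera adjusted p = 0.000255, adjusted p = 0.0253 with an estimated correlation), with ASCL2 and the crypt marker SMOC2 (-0.73) as examples.

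Another 8 lists passed camera's test under pioglitazone at the preset correlation and did not at an estimated one. Enterocyte brush border and lipid transport genes rose, 12 of 29 higher and 3 lower (13 and 3 adjusted over the list alone). The median log2 ratio was 0.04 (camera adjusted p = 0.0171, adjusted p = 0.399 with an estimated correlation), with LCT up and SI down. Cholesterol genes rose, 11 of 25 higher and 0 lower (12 adjusted over the list alone). Over the list the median was 0.11 (camera adjusted p = 0.0015, adjusted p = 0.238 with an estimated correlation), with FDFT1, which makes squalene, at 0.45 and the sterol sensor INSIG1 at 0.41. Cell cycle genes fell, 18 of 35 lower and 1 higher (19 and 1 adjusted over the list alone). On the log2 scale the median was -0.11 (camera adjusted p = 0.000159, adjusted p = 0.296 with an estimated correlation), with UHRF1 at -0.37, and the exception was the replication helicase subunit MCM6 at 0.42. Heat shock and metallothionein genes fell, 11 of 18 lower and 1 higher (12 and 1 adjusted over the list alone). Their median was -0.21 (camera adjusted p = 0.000159, adjusted p = 0.238 with an estimated correlation), with the largest falls in MT2A and MT1X (-0.87). Interferon response genes rose, 6 of 15 higher and 1 lower (7 and 1 adjusted over the list alone). The list median was 0.11 (camera adjusted p = 0.0022, adjusted p = 0.243 with an estimated correlation), with the antiviral sensor OAS1 up 2.69-fold and MX1, not well above background in the control pool, up at least 1.57-fold. Tight and adherens junction genes rose, 9 of 18 higher and 1 lower (10 and 1 adjusted over the list alone). The genes had a median of 0.13 (camera adjusted p = 0.00283, adjusted p = 0.243 with an estimated correlation), with the channel-forming claudin CLDN2 up 2.23-fold and TJP3 at 0.36. Against the control pool of the 30 mM treatments the junction median was -0.00 (SE 0.0714) and the interferon median 0.04 (SE 0.0966). Of single genes, MT2A had -0.60, MT1X -0.37 and UHRF1 -0.10 against that pool, so the size of these falls depends on the pool, while OAS1 kept 1.31 and CLDN2 1.04.

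Hypoxia and iron response genes rose under pioglitazone, 15 of 22 higher and 2 lower (15 and 2 adjusted over the list alone). The median log2 ratio was 0.25 (camera adjusted p = 0.000255, adjusted p = 0.462 with an estimated correlation), with NDRG1, a hypoxia-induced stress protein, up 2.58-fold and the carbonic anhydrase CA12 up 1.47-fold. Glycolysis and glucose transport genes rose, 8 of 15 higher and 1 lower (8 and 1 adjusted over the list alone). Over the list the median was 0.18 (camera adjusted p = 0.037, adjusted p = 0.482 with an estimated correlation), with the glycolytic enzymes ALDOA at 0.41 and GPI at 0.25. The glycolysis call ended without pioglitazone replicate 1 (median 0.15, adjusted p = 0.0914). Set against the pool of the 30 mM treatments on the same slides, pioglitazone wells gave medians of 0.01 (SE 0.0683) for hypoxia genes and 0.04 (SE 0.033) for glycolysis genes. Both medians in that setting lay within 2 standard errors of 0, taken over genes, which are not independent replicates.

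**Figure D1:**
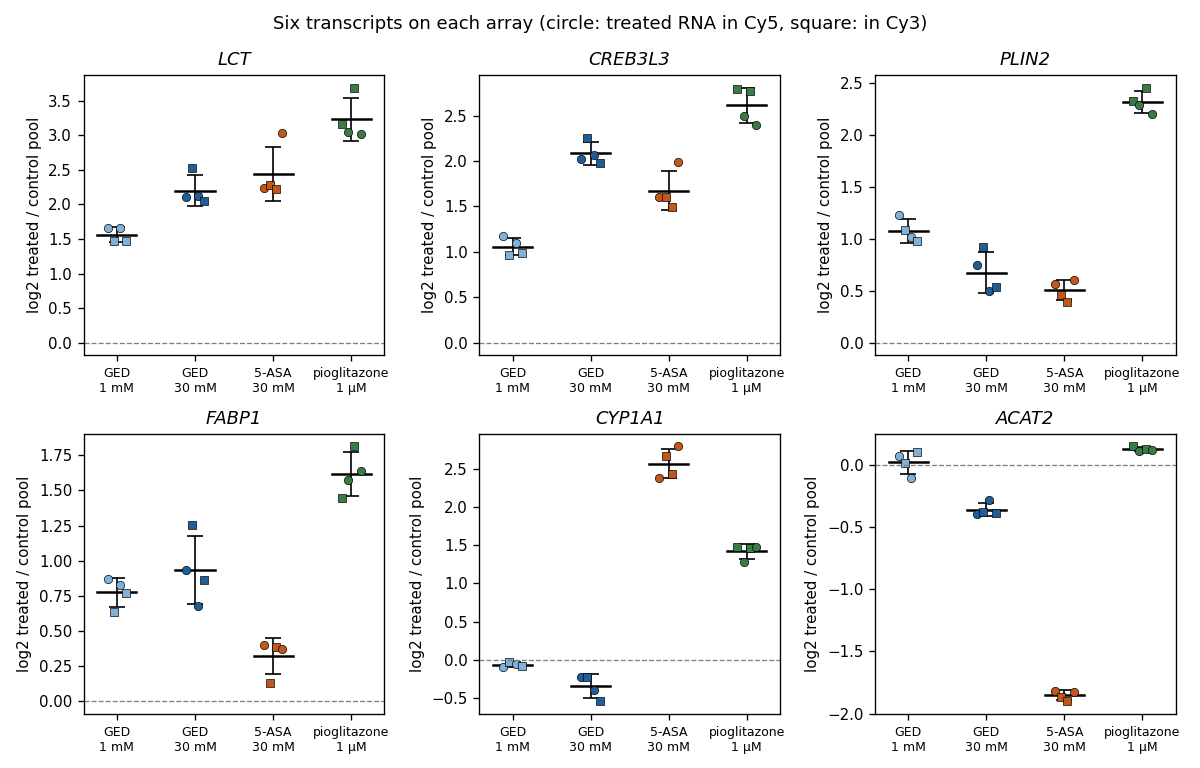
Each panel plots 1 transcript on the 16 arrays: the vertical axis is the log2 ratio of treated RNA to its control pool after removal of the fitted dye effect, points are arrays (circle, treated RNA in Cy5; square, in Cy3), horizontal bars are means and whiskers standard deviations over 4 arrays. LCT lies above 0 on every array, at a mean of 1.56 for GED 1 mM and 3.23 for pioglitazone, and ACAT2 lies far below 0 under 5-ASA, at -1.85.

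GED at 1 mM asked what the lower dose of this compound does, and the genes that rose most overlapped those of pioglitazone, at smaller sizes. LCT rose 2.96-fold (log2 1.56, SE 0.119, n = 4 arrays, adjusted p = 2.41e-07), PLIN2 2.11-fold (SE 0.0621 on the log2 scale) and CREB3L3 2.08-fold (SE 0.0735). GPA33 rose 2.03-fold, SGK2 1.99-fold, SLC51A 1.94-fold and FABP1 1.71-fold. Weaker further probes gave 0.05 for GPA33, 0.24 for CREB3L3, -0.23 for ENC1, -0.25 for CDH7 and -0.03 for MT1X. The largest falls were under 2-fold: ENC1 at -0.49, CDH7 at -0.45, ANKRD1 and RAMP1 at -0.43, SOX2 at -0.42, and MT1X and TNFRSF11B at -0.39. With control wells given the spread of the arrays the calls of ENC1, CDH7, ANKRD1, MT1X, TNFRSF11B and SLC51A ended, and those of ANKRD1, MT1X and SLC51A also ended with the local backgrounds kept as scanned. In all, 1891 genes changed, 1125 higher and 766 lower, and 6 rose and 0 fell at least 2-fold. The same simulations of unchanged wells called a median of 1026.5 genes for this treatment, with 2 control wells assumed in its pool. The count was 596 without replicate 1, 926 without replicate 2 and 1085 without replicate 4. It was 298 with the backgrounds kept, a setting that hardly moved the spreads of these 4 arrays, and 95 with control wells given a spread. With each array centred on its median 93.6% of the called genes were higher, against 59.5%. Over all kept probes, arrays of opposite dye correlated at -0.179 to 0.0441 and arrays of the same dye at 0.690 to 0.741. The dye effect was not removed for these values, which by itself lowers those of opposite dye and raises those of the same dye. All 4 arrays lay on a slide and scan day of their own, so slide, scan day, pool and treatment cannot be told apart here.

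PPAR targets rose under GED 1 mM, 20 of 32 higher and 2 lower (20 and 2 adjusted over the list alone). On the log2 scale the median was 0.23 (camera adjusted p = 1.14e-16, adjusted p = 0.0158 with an estimated correlation). Of the receptors, PPARG had -0.10 (adjusted p = 0.0977), PPARA 0.09 (adjusted p = 0.272), PPARD -0.09 (adjusted p = 0.135) and RXRA 0.00 (adjusted p = 0.955). ANGPTL4 had 0.07 (adjusted p = 0.407), and PDK4 was not well above background in either channel. Wnt targets fell, 6 of 19 lower and 0 higher (11 adjusted over the list alone). Their median was -0.12 (camera adjusted p = 1.08e-05, adjusted p = 0.00555 with an estimated correlation), with LEF1 at -0.36 and ASCL2 at -0.28. Their second probes gave -0.12 and -0.04. The calls of LEF1 and ASCL2 ended with the backgrounds kept or with control wells given a spread.

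A further 5 lists passed for GED 1 mM, each at camera adjusted p = 0.0347 and none with an estimated correlation. PXR and bile acid receptor targets had 3 of 9 higher and 0 lower (4 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation), among them SLC51B, partner of SLC51A, at 0.43 and CYP2B6 at 0.37. NRF2 targets had 7 of 21 higher and 0 lower (8 adjusted over the list alone; adjusted p = 0.727 with an estimated correlation), among them the reductase AKR1C1 at 0.46 and the efflux pump ABCC3 at 0.38. Tight and adherens junction genes had 7 of 18 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.697 with an estimated correlation), among them the claudin CLDN1 at 0.23. Cell cycle genes had 8 of 35 lower and 2 higher (11 and 3 adjusted over the list alone; adjusted p = 0.727 with an estimated correlation), with CDT1 at -0.24 and, opposite to the list, TOP2A at 0.37. Heat shock and metallothionein genes had 6 of 18 lower and 1 higher (6 and 2 adjusted over the list alone; adjusted p = 0.727 with an estimated correlation), with MT1G at -0.34 and the small heat shock protein HSPB1 at -0.23. Weaker further probes gave 0.05 for CYP2B6, 0.02 for AKR1C1, 0.03 for CLDN1 and -0.19 for MT1G. Without replicate 3 the PXR (adjusted p = 0.0638), junction (0.0638), cell cycle (0.29) and heat shock (0.138) calls ended, and without replicate 4 the PXR (0.0509), NRF2 (0.0789), junction (0.0509) and heat shock (0.0618) calls ended. MT1G lost its call without replicate 1 (-0.30, adjusted p = 0.0506). All 5 list calls ended with the processed log ratios of the scanner, and the PXR and cell cycle calls also ended with median centring. Given a spread between control wells, the calls of ABCC3, TOP2A, CDT1, CLDN1, HSPB1 and MT1G ended, and those of CLDN1 and MT1G ended with the backgrounds kept and those of CDT1 and HSPB1 with median centring. The CLDN1 call also ended with the mean over probes, and that of CDT1 with no dye term.

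GED at 30 mM asked what the higher dose of this compound does. G0S2, an inhibitor of triglyceride breakdown, rose 5.61-fold (log2 2.49, SE 0.0605, n = 4 arrays, adjusted p = 1.94e-15), GSTA2 4.96-fold, GSTA5 4.86-fold, GSTA1 4.76-fold, GSTA3 4.24-fold, the RNA-binding protein CELF3 4.79-fold and LCT 4.6-fold (log2 2.2, SE 0.119). The GSTA genes are near-identical copies, so their probes are not certain to tell them apart. EGR1, a transcription factor induced by growth signals, was 11.6-fold lower (log2 -3.54, SE 0.0733, adjusted p = 3.81e-16), the ERK phosphatase DUSP6 7.01-fold, the focal adhesion protein TNS4 6.92-fold, MYC 6.79-fold, IER3 5.90-fold, the glucose transporter SLC2A1 5.77-fold and the collagenase MMP1 4.96-fold lower. For MYC 1 of 3 probes gave 0.01. In all 9221 genes changed, 4914 higher and 4307 lower, and 98 rose and 132 fell at least 2-fold. Simulated unchanged wells gave a median of 1014.5 calls for GED 30 mM. Against the pioglitazone pool 8710 of the 9221 called genes (94.5%) kept their sign. Weaker further probes gave -1.01 for SLC2A1 and, for genes named below, 0.63 for CREB3L3, 0.62 for CPT1A and 0.24 for AKR1C1.

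PPAR targets rose under GED 30 mM, 21 of 32 higher and 3 lower (21 and 3 adjusted over the list alone). The list median was 0.33 (camera adjusted p = 9.22e-05, adjusted p = 0.226 with an estimated correlation), with CREB3L3 up 4.23-fold and CPT1A, the gate of mitochondrial fatty acid entry, up 1.91-fold. FABP1 rose 1.91-fold, PLIN2 1.6-fold and PDK4 at least 1.47-fold, while ANGPTL4 had 0.05 (adjusted p = 0.373). PPARG fell by 1.11 (SE 0.0387, adjusted p = 1.42e-13) and PPARD by 0.15, PPARA had -0.01 (adjusted p = 0.888), and RXRA rose by 0.69 with 1 of its 3 probes at -0.22. NRF2 targets rose, 12 of 21 higher and 3 lower (12 and 3 adjusted over the list alone). The genes had a median of 0.13 (camera adjusted p = 0.0274, adjusted p = 0.583 with an estimated correlation), with AKR1C1 up 3.47-fold and PIR up 1.83-fold. The NRF2 call ended with the processed log ratios of the scanner. The PPARD call ended with the backgrounds kept or with control wells given a spread.

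Wnt targets fell under GED 30 mM, 17 of 19 lower and 0 higher (17 lower and 1 higher adjusted over the list alone). The median log2 ratio was -0.49 (camera adjusted p = 1.91e-07, adjusted p = 0.0017 with an estimated correlation), with MYC and the cyclin CCND1 (-1.43) as examples. Immediate early genes fell, 15 of 17 lower and 0 higher (15 adjusted over the list alone). Over the list the median was -1.03 (camera adjusted p = 1.69e-08, adjusted p = 0.206 with an estimated correlation), with EGR1 and MYC in front. Hypoxia and iron response genes fell, 19 of 22 lower and 1 higher (19 and 2 adjusted over the list alone). On the log2 scale the median was -0.49 (camera adjusted p = 5.17e-07, adjusted p = 0.356 with an estimated correlation), with SLC2A1 and hexokinase HK2 (-2.02) in front. Glycolysis and glucose transport genes fell, 12 of 15 lower and 2 higher (12 and 2 adjusted over the list alone). Their median was -0.70 (camera adjusted p = 9.22e-05, adjusted p = 0.226 with an estimated correlation), with ENO1 at -0.97 and PGAM1 at -0.87. Against the pioglitazone pool these medians were -0.28 (SE 0.134) for hypoxia and -0.49 (SE 0.101) for glycolysis. Goblet and secretory markers fell, 11 of 14 lower and 0 higher (11 adjusted over the list alone). The list median was -0.37 (camera adjusted p = 0.000116, adjusted p = 0.199 with an estimated correlation), with REG4 at -2.14 and the mucin-folding protein AGR2 at -1.05. Stem cell markers fell, 7 of 10 lower and 2 higher (7 and 2 adjusted over the list alone). The genes had a median of -0.50 (camera adjusted p = 0.0103, adjusted p = 0.199 with an estimated correlation), with SMOC2 at -1.73 and CD44 at -0.79.

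5-ASA at 30 mM asked what this drug does at the same dose and time, and it moved the most genes. AKR1C1 rose 12-fold (log2 3.58, SE 0.0471, n = 4 arrays, adjusted p = 1.55e-19), ATF3, a stress-induced transcription factor, 9.14-fold, AASS, an enzyme of lysine breakdown, 8.94-fold, the glutamate transporter SLC1A3 8.56-fold, CYP1A1, a drug-metabolizing enzyme, 5.95-fold, and the matrix protein CCN2 5.67-fold. TESMIN had the largest rise, 25.1-fold, on 1 probe, while its other probe gave -0.06. The largest falls were in EGR1 at -3.71, the mitochondrially encoded COX3 at -3.82 and ND3 at -3.18, the water channel AQP10 at -2.99 (its other probe at -0.47), MMP1 at -2.90, SLC2A1 at -2.72 and TNS4 at -2.68. LCT rose 5.43-fold (log2 2.44, SE 0.119). In all 11462 genes changed, 5435 higher and 6027 lower, and 552 rose and 678 fell at least 2-fold. Simulated unchanged wells gave a median of 1024 calls for 5-ASA. Against the pioglitazone pool 11114 of the 11462 called genes (97.0%) kept their sign. Weaker further probes gave 0.59 for AKR1C1, 1.34 for ATF3, -0.90 for SLC2A1 and, for genes named below, -0.31 for ASCL2 and 0.93 for HSPA1A.

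Genes of cholesterol synthesis and uptake fell under 5-ASA, 24 of 25 lower and 1 higher (24 and 1 adjusted over the list alone). The median log2 ratio was -0.98 (camera adjusted p = 5.92e-08, adjusted p = 0.0419 with an estimated correlation). ACAT2, an acetyl-CoA acetyltransferase of the cytosol, was 3.61-fold lower (log2 -1.85, SE 0.0352). Fatty acid synthesis genes fell, 11 of 15 lower and 3 higher (11 and 3 adjusted over the list alone). Over the list the median was -0.60 (camera adjusted p = 0.0242, adjusted p = 0.155 with an estimated correlation), with the lipogenic transcription factor SREBF1 at -1.70 and PNPLA3 at -1.65. AhR targets rose, 6 of 8 higher and 1 lower (6 and 1 adjusted over the list alone). On the log2 scale the median was 0.85 (camera adjusted p = 0.0192, adjusted p = 0.214 with an estimated correlation), with CYP1A1 and the conjugating enzyme UGT1A6 (1.36). NRF2 targets rose, 16 of 21 higher and 3 lower (16 and 3 adjusted over the list alone). Their median was 0.70 (camera adjusted p = 0.000231, adjusted p = 0.325 with an estimated correlation), with AKR1C1 and the efflux pump ABCC2, 5.15-fold higher. Heat shock and metallothionein genes rose, 12 of 18 higher and 3 lower (12 and 3 adjusted over the list alone). The list median was 0.63 (camera adjusted p = 0.0218, adjusted p = 0.479 with an estimated correlation), with HSPA1A at 1.48 and the zinc exporter SLC30A1 at 1.24. HSPA1A has a near-identical copy, HSPA1B, and AKR1C1 has close relatives, so their probes are not certain to read 1 gene alone. CYP1A1 also rose under pioglitazone, by 1.27 to 1.47 on the log2 scale on its 4 arrays after removal of the fitted dye effect. The AhR list was not called under pioglitazone (median -0.05, camera adjusted p = 0.952).

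Wnt targets fell under 5-ASA, 14 of 19 lower and 2 higher (14 and 2 adjusted over the list alone). The genes had a median of -0.67 (camera adjusted p = 0.00328, adjusted p = 0.0419 with an estimated correlation), with ASCL2 at -1.72 and the receptor EPHB2 at -1.41. Hypoxia and iron response genes fell, 18 of 22 lower and 1 higher (18 and 1 adjusted over the list alone). The median log2 ratio was -0.93 (camera adjusted p = 0.00115, adjusted p = 0.486 with an estimated correlation), with lactate dehydrogenase LDHA at -2.41, and the riser was the peptide hormone ADM at 1.65. Glycolysis and glucose transport genes fell, 14 of 15 lower and 1 higher (14 and 1 adjusted over the list alone). Over the list the median was -0.87 (camera adjusted p = 0.000529, adjusted p = 0.309 with an estimated correlation), with PGAM1 at -1.53 and GPI at -1.44. Against the pioglitazone pool the medians were -0.72 (SE 0.202) for hypoxia and -0.77 (SE 0.139) for glycolysis. Goblet and secretory markers fell, 12 of 14 lower and 2 higher (12 and 2 adjusted over the list alone). On the log2 scale the median was -0.39 (camera adjusted p = 0.0352, adjusted p = 0.479 with an estimated correlation), with TFF1 at -1.45 and KLK1 at -1.13. PPAR targets went both ways, 11 of 32 higher and 13 lower (11 and 13 adjusted over the list alone), with a median of 0.06, a mean of -0.10 and a camera direction of down (adjusted p = 0.884). PLIN2 rose by 0.50, FABP1 by 0.32, ANGPTL4 by 0.49 and PDK4 at least 1.37-fold. PPARG fell by 1.29 (SE 0.0387, adjusted p = 1.62e-15), PPARA rose by 0.33 with 1 of 4 probes opposite, PPARD fell by 0.25 with 1 of 2 probes opposite, and RXRA had -0.02 (adjusted p = 0.625), while another RXRA probe gave -0.63.

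**Figure D2:**
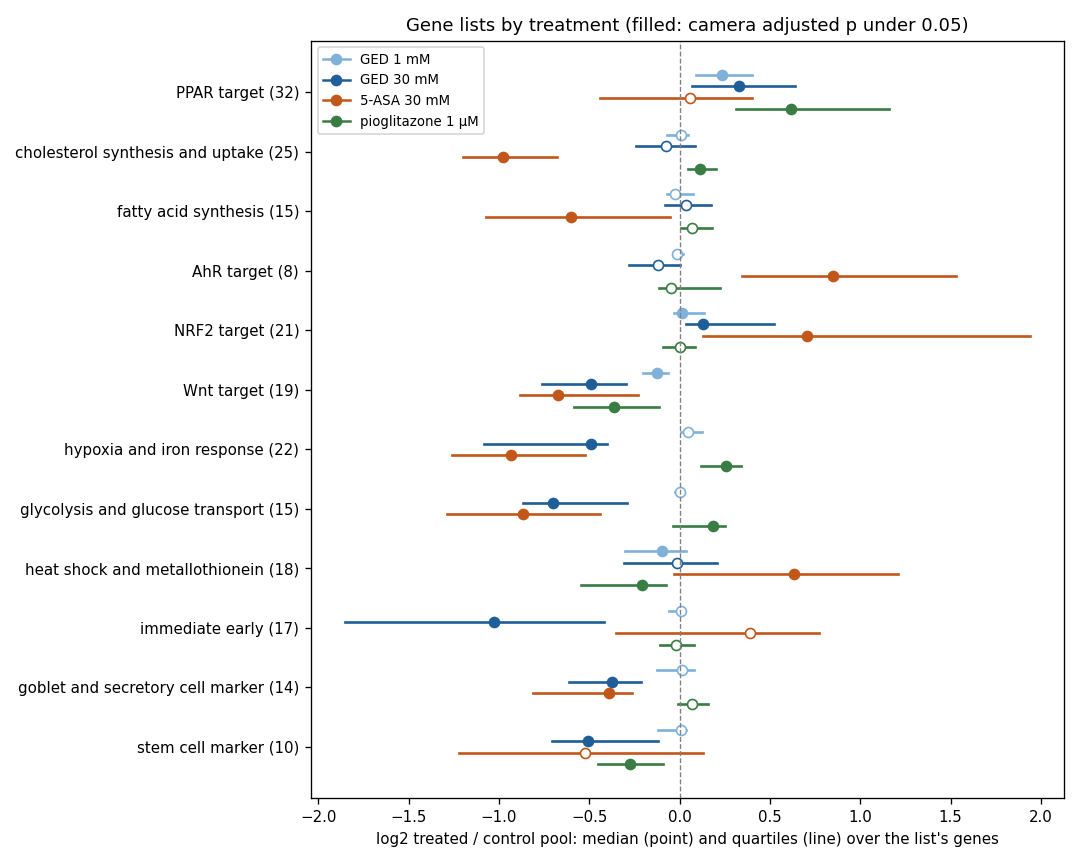
The plot gives, for 12 gene lists and 4 treatments, the median (point) and quartiles (line) of the log2 ratio to the control pool over the measured genes of a list, with filled points where camera's adjusted p was under 0.05 at the preset correlation. Wnt targets lie left of 0 in all 4 treatments, from -0.12 to -0.67, and cholesterol genes lie at -0.98 under 5-ASA.

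GED and 5-ASA at 30 mM were set against each other directly, at matched dose and time and with the same control pool, which cancels in the difference. Values are GED minus 5-ASA over 8 arrays. COX3 was 3.88 higher under GED on the log2 scale (SE 0.164, adjusted p = 1.31e-12), ND3 3.25, ATP6 2.26 and COX2 2.16 higher, all of them mitochondrially encoded, and the methyltransferase TMT1A 2.35, the RNA decapping enzyme DCPS 2.31 and CLRN3 2.26 higher. TESMIN was lower by -3.91 (with its other probe at 0.37), the receptor GPRC5A by -3.61, AASS by -3.43, CYP1A1 by -2.92, the transcription factor JUN by -2.82, and the MAP kinase phosphatases DUSP6 by -2.70 and DUSP5 by -2.70. In all 9408 genes differed, 5182 higher and 4226 lower under GED, and 359 and 312 at least 2-fold. Weaker further probes gave 0.74 for TMT1A, -1.85 for GPRC5A and, for genes named below, 0.95 for MVK, 1.11 for SREBF1, 0.27 for ACSL3, -0.40 for MT1G, 0.07 for RXRA and -0.35 for AKR1C1. With slide as a fixed block the count was 9163. On the 3 slides that held both, 98.0% to 99.8% of the differing genes kept their sign, a share made high by picking those genes on the same arrays.

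Cholesterol genes were higher under GED than under 5-ASA, 24 of 25 higher and 0 lower (24 and 1 adjusted over the list alone). Their median was 0.84 (camera adjusted p = 6.06e-10, adjusted p = 0.0352 with an estimated correlation), with the mevalonate kinase MVK at 1.51. Fatty acid synthesis genes were higher, 10 of 15 against 1 lower (10 and 1 adjusted over the list alone). The list median was 0.81 (camera adjusted p = 0.00188, adjusted p = 0.0352 with an estimated correlation), with PNPLA3 at 1.80 and SREBF1 at 1.67. PPAR targets were higher, 24 of 32 against 3 lower (24 and 3 adjusted over the list alone). The genes had a median of 0.42 (camera adjusted p = 0.000283, adjusted p = 0.289 with an estimated correlation), with ACSL3 at 1.88 and ECH1 at 1.27. AhR targets were lower, 7 of 8 and 0 higher (7 adjusted over the list alone). The median log2 ratio was -0.85 (camera adjusted p = 0.000133, adjusted p = 0.0352 with an estimated correlation), with CYP1A1 and NFE2L2 (-1.04). NRF2 targets were lower, 14 of 21 against 3 higher (14 and 3 adjusted over the list alone). Over the list the median was -0.35 (camera adjusted p = 0.000283, adjusted p = 0.331 with an estimated correlation), with SRXN1 at -2.13 and TXNRD1 at -2.03. Heat shock and metallothionein genes were lower, 15 of 18 against 2 higher (15 and 2 adjusted over the list alone). On the log2 scale the median was -0.48 (camera adjusted p = 0.000378, adjusted p = 0.281 with an estimated correlation), with HSPA1A at -1.72 and MT1G at -1.02. Immediate early genes were lower, 15 of 17 and 0 higher (15 adjusted over the list alone). Their median was -1.49 (camera adjusted p = 8.75e-09, adjusted p = 0.206 with an estimated correlation), with JUN and DUSP5 in front. Within each of the 3 slides the median of each of these 7 lists kept its sign, at 0.85 to 0.91 for cholesterol genes and -1.32 to -1.46 for immediate early genes. The lists were called on the same arrays, so the kept signs are not a separate test.

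Several genes did not pass the test of this difference. LCT differed by -0.24 (95% interval -0.59 to 0.12, adjusted p = 0.228), PLIN2 by 0.17 (-0.01 to 0.36), PPARD by 0.10 (-0.01 to 0.21), PDK4 by 0.06 (-0.14 to 0.26), MBL2 by -0.05 (-0.21 to 0.11) and LOC100507307 by -0.10 (-0.29 to 0.10). FABP1 was higher under GED by 0.61, CREB3L3 by 0.41, SMOC2 by 0.36, PPARG by 0.18 and RXRA by 0.71. ANGPTL4 was lower by -0.44, PPARA by -0.34, AKR1C1 by -1.79, SLC1A3 by -1.98 and HMOX1 by -1.41. AADAC differed by 0.24 (adjusted p = 0.0406), which ended without any 1 of 6 arrays, GED 30 mM replicates 1, 2 and 4 and 5-ASA replicates 1 to 3 (adjusted p = 0.071 to 0.142), and in 12 alternatives in all. SLC12A2 differed by 0.11 (adjusted p = 0.0322), which ended without GED replicate 1 (adjusted p = 0.0822), GED replicate 4 (0.0729) or 5-ASA replicate 3 (0.0965), and the other SLC12A2 probe gave -0.68. In all 10 alternatives ended it. The PPARG difference ended with no dye term, and the PPARG and SMOC2 differences ended with the backgrounds kept.

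**Figure D3:**
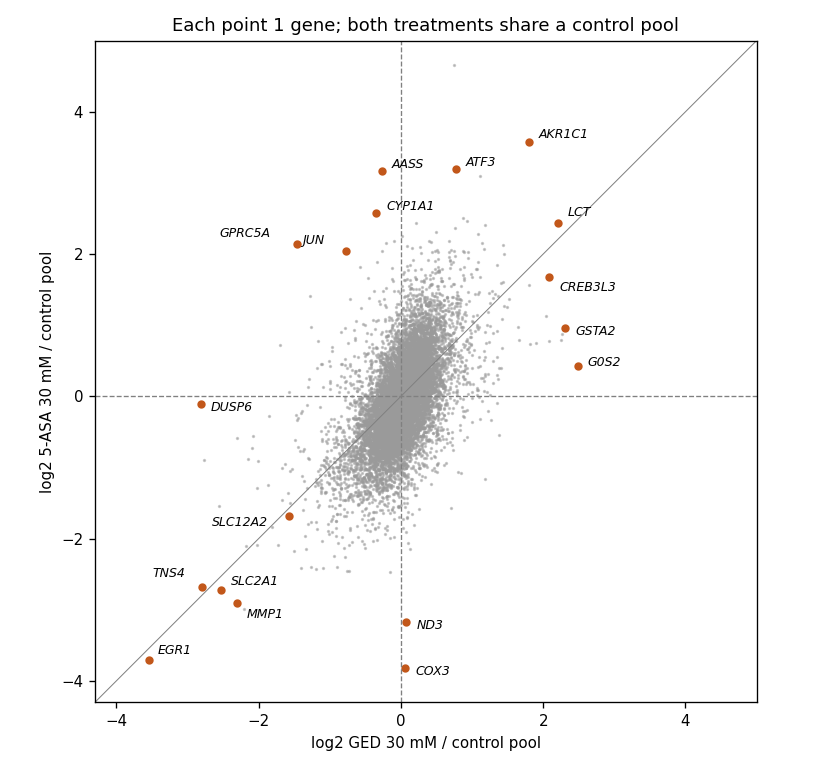
Each point is 1 of 14515 genes, with its log2 ratio to the shared control pool under GED 30 mM on the horizontal axis and under 5-ASA 30 mM on the vertical axis, and the diagonal marks equal ratios. EGR1 lies low on both axes (-3.54 and -3.71), while COX3 and AASS lie far from the diagonal.

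The fold changes of GED 30 mM and 5-ASA were correlated across genes, which are not independent replicates (Pearson r = 0.569, Spearman rho = 0.570), with 3204 genes higher in both, 3223 lower in both and 1526 opposite. The shared pool adds to this: unchanged groups simulated against it gave a median r of 0.667, 185 genes higher in both and 180 lower in both. Over all genes 70.6% had the same sign in both treatments, against a median of 73.2% in the simulation. Neither r nor this share lay above the simulated values, which decides nothing about how far the treatments agree. In unchanged groups r and this share are set by the numbers of control wells and arrays put into the simulation. They are therefore no measure for groups that hold changes. The covariance was 0.108 against 0.00477 in the simulation, a difference of 0.104. The pool cannot be split, so part of the excess in the overlap can come from it.

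The doses of GED were set against each other with their pools as part of the contrast. EGR1 was lower at 30 mM by -3.31, DUSP6 by -3.05, TNS4 by -2.79 and MYC by -2.75 on the log2 scale, and G0S2 was 2.54 and CELF3 2.05 higher. LCT rose at both doses, 2.96-fold at 1 mM and 4.6-fold at 30 mM. In all 7297 genes differed, 3842 higher and 3455 lower at 30 mM, and 66 and 113 at least 2-fold. The count was 3829 with the backgrounds kept and 3556 with control wells given a spread. With arrays centred on their medians 41.0% of the differing genes were higher, against 52.7%. Lower at 30 mM were Wnt targets (14 of 19, and 14 adjusted over the list alone; camera adjusted p = 9.63e-06, adjusted p = 0.00611 with an estimated correlation) and hypoxia genes (20 of 22, and 20 adjusted over the list alone; adjusted p = 0.283 with an estimated correlation). Also lower were immediate early genes (15 of 17, and 15 adjusted over the list alone; adjusted p = 0.133 with an estimated correlation) and glycolysis genes (11 of 15, and 11 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation). Goblet markers (11 of 14, and 11 adjusted over the list alone) and stem cell markers (6 of 10, and 6 adjusted over the list alone) were lower as well, each with adjusted p = 0.133 with an estimated correlation. PPAR targets had 9 of 32 higher and 8 lower at 30 mM (9 and 8 adjusted over the list alone; camera adjusted p = 0.569). The slide of GED 1 mM held no other treatment, so slide and dose cannot be told apart in these differences.

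Genes that changed the same way in all 4 treatments numbered 442, with 259 higher and 183 lower, out of 811 genes called in all 4. The rest of the 811 went in mixed directions. Because GED 30 mM and 5-ASA share a pool, these lists are not independent, and no value for unchanged groups was computed for this count. LCT led, followed by CREB3L3, and both rose in every treatment, CREB3L3 by 1.06 (GED 1 mM), 2.08 (GED 30 mM), 1.67 (5-ASA) and 2.61 (pioglitazone) on the log2 scale. In the same order AADAC, a lipid and drug esterase, rose by 0.86, 1.49, 1.26 and 1.75, MBL2, a lectin of innate immunity, by 0.75, 1.36, 1.41 and 1.46, and LOC100507307 by 1.01, 1.29, 1.38 and 2.13. HMOX1, which breaks down heme, rose by 0.51, 0.52, 1.94 and 1.77, SLC1A3 by 0.46, 1.12, 3.1 and 0.92, and AKR1C1 by 0.46, 1.79, 3.58 and 0.16. SLC12A2 had -0.33, -1.57, -1.69 and -1.12, and SMOC2 had -0.26, -1.73, -2.09 and -0.73. A second SLC1A3 probe gave 0.04 under GED 30 mM, and a second MBL2 probe 0.31, 0.74, 0.58 and 0.67 in the same order. The AKR1C1 rise under pioglitazone ended without replicate 3 (0.15, adjusted p = 0.0541) or replicate 4 (0.11, adjusted p = 0.113). It also ended with the processed log ratios, the deposited table, median centring or control wells given a spread. The GED 1 mM calls of HMOX1 and SMOC2 ended with the backgrounds kept or with control wells given a spread, and that of SLC12A2 with the backgrounds kept. The count of 442 was 45 with control wells given a spread, 88 with the backgrounds kept and 182 with no dye term, and it was 223 without GED 1 mM replicate 1 and 293 without replicate 2. With arrays centred on their medians 87.1% of the shared genes were higher, against 58.6%.

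GED 1 mM and pioglitazone, which share neither pool nor slide, overlapped most closely in sign. Of 1140 genes called in both, 90.9% had the same sign, with 678 higher in both, 358 lower in both and 104 opposite, where independence would give 211, 147 and 360. Across genes, which are not independent replicates, r was 0.547 and rho 0.297. Of 71 genes that pioglitazone raised at least 2-fold, 65 were called higher under GED 1 mM. These overlap counts rest on the GED 1 mM calls, which numbered 596 without its replicate 1, fewer than the 1140 called in both. Those calls fell further with the backgrounds kept or with control wells given a spread, and the overlap was not counted in these settings. The ratios differed for 3417 genes, 1721 higher and 1696 lower under GED (84.1% higher with arrays centred on their medians, against 50.4%). The count was 904 with the backgrounds kept, 433 with control wells given a spread and 1334 with no dye term. PPAR targets were lower under GED 1 mM than under pioglitazone, 23 of 32 and 0 higher (26 adjusted over the list alone; camera adjusted p = 6.59e-18, adjusted p = 0.0122 with an estimated correlation). Wnt targets were higher, 10 of 19 and 0 lower (10 adjusted over the list alone; adjusted p = 0.0122 with an estimated correlation), and stem cell markers were higher, 5 of 10 and 0 lower (5 adjusted over the list alone; adjusted p = 0.0297 with an estimated correlation). The other 6 lists called in this pair, cholesterol, cell cycle, hypoxia, glycolysis, heat shock and interferon genes, had adjusted p of 0.21 to 0.638 with an estimated correlation.

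The remaining pairs had weaker or no overlap. GED 1 mM and GED 30 mM shared 674 genes higher and 446 lower (expected 381 and 227, r = 0.292), and GED 1 mM and 5-ASA 535 and 474 (expected 421 and 318, r = 0.148). These counts must shrink without GED 1 mM replicate 1, where only 596 genes in all were called for GED 1 mM. GED 30 mM and pioglitazone shared 1095 and 1102 (expected 922 and 827, r = 0.138), with 1866 opposite (expected 1752), and 5-ASA and pioglitazone shared 906 and 1266 (expected 1020 and 1158, r = -0.022), with 2490 opposite (expected 2175). GED 30 mM differed from pioglitazone at 8295 genes (5065 with the backgrounds kept, 5241 with control wells given a spread) and in 7 lists, 5-ASA from pioglitazone at 10694 genes and in 9 lists, and 5-ASA from GED 1 mM at 10405 genes and in 10 lists, and 0 of these list calls held with an estimated correlation (by camera at the preset correlation, 7, 9 and 10). PPAR targets were lower than under pioglitazone in 22 of 32 genes for GED 30 mM (23 adjusted over the list alone; camera adjusted p = 2.93e-05, adjusted p = 0.211 with an estimated correlation) and in 26 for 5-ASA (26 adjusted over the list alone; camera adjusted p = 3.02e-05, adjusted p = 0.241 with an estimated correlation). The pools are part of these differences. Against the pioglitazone pool the PPAR medians were 0.61 for pioglitazone, 0.49 (SE 0.101) for GED 30 mM and 0.20 (SE 0.144) for 5-ASA. Against the shared pool they were 0.42 (SE 0.114), 0.33 and 0.06 in the same order. The gaps were thus narrower against a common pool than with each treatment's own. With slide as a fixed block, 8993 genes were called for GED 30 mM, 11338 for 5-ASA and 5169 for pioglitazone. Within each of the 3 slides these treatments share, 98.1% to 100% of called genes kept their sign. All 35 called list medians of these 3 treatments and of the 30 mM difference kept their sign within each slide, and none moved by more than 0.0269 with slide as a block. Genes and lists were called on these same arrays, so agreement in sign within slides is largely built in and does not test slide.

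Transcripts encoded by the mitochondrial chromosome were unequal under 5-ASA. Of 10 such genes with a probe on that chromosome (coordinates in hg19 as the files give them), COX3 (9410 to 9469) was at -3.82, ND3 (10345 to 10404) at -3.18, ATP6 (8836 to 8895) at -2.14, COX2 (7987 to 8046) at -2.06, CYTB (15588 to 15646) at -1.91 and ND6 (14449 to 14508), read from the opposite strand, at -1.80. ND5 (13887 to 13946) rose by 1.40 (SE 0.121) and ND2 (4914 to 4973) by 0.56, ND1 (4181 to 4240) fell by 0.43, and ND4 had 0.11 (adjusted p = 0.349). A second ND3 probe was at -2.35 and a second CYTB probe at -2.25, and COX3, ATP6, COX2 and ND6 had 1 probe each. The COX1 probe (-0.05, adjusted p = 0.739) lies on chromosome 1, from 567567 to 567626, so it is not certain to read the mitochondrial transcript. These genes were picked out after their values were seen, except COX3, ND3, ATP6 and COX2, which the naming rule chose.

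**Figure D4:**
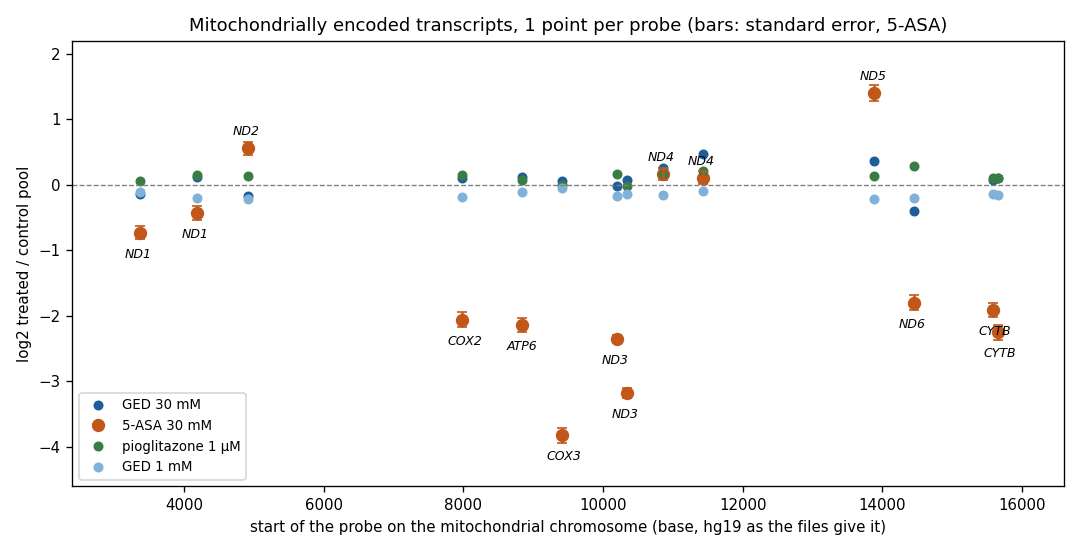
Points are probes on the mitochondrial chromosome, placed by start position (hg19 as the files give it), with the log2 ratio to the control pool on the vertical axis for 4 treatments and standard errors for 5-ASA. Under 5-ASA, COX3 at -3.82 and ND3 at -3.18 lie lowest and ND5 at 1.40 lies highest, while the GED 30 mM points lie between -0.40 and 0.47.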

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

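In this part the tests of the control pools were chosen before their result was seen, and the pattern that led to them was seen first.

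Hypoxia and glycolysis genes went opposite ways, down under both 30 mM treatments and up under pioglitazone. Between GED 30 mM and pioglitazone the hypoxia list had camera adjusted p = 8.15e-09 (median difference -0.98, adjusted p = 0.273 with an estimated correlation), and between 5-ASA and pioglitazone 0.000259 (-1.28, adjusted p = 0.503 with an estimated correlation). For the glycolysis list these were 4.76e-05 (-0.98, adjusted p = 0.211 with an estimated correlation) and 0.00025 (-1.12, adjusted p = 0.268 with an estimated correlation). Standard errors in this paragraph are over genes, which are not independent replicates, and do not measure the spread between wells. The first reading is that the pool shared by both 30 mM treatments stood apart. Over 37 genes of both lists that pool was 0.168 (SE 0.0226) above the pioglitazone pool on the same slides, 35 of them higher, which is less than the -0.286 that makes up 50% of the GED fall, so in these values the pool does not account for the whole fall of the 2 lists together. For the 22 hypoxia genes alone it was 0.203 (SE 0.026), within 2 standard errors of 50% of their GED fall (-0.244), so the share of the pool in that fall stays open. Against the pioglitazone pool, GED 30 mM wells still had -0.41 (SE 0.0892) over both lists and 5-ASA wells -0.735 (SE 0.131), while pioglitazone wells against the shared pool had 0.0285 (SE 0.0427), so the rise under pioglitazone may come from the pools, and only control wells kept apart would tell.

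Cholesterol genes also went opposite ways, down under 5-ASA and up under pioglitazone, with camera adjusted p = 7.27e-09 for the difference (median -0.98, adjusted p = 0.0552 with an estimated correlation). Heat shock and metallothionein genes rose under 5-ASA and fell under pioglitazone (0.00211, median 0.80, adjusted p = 0.278 with an estimated correlation) and under GED 1 mM (0.00584, median 0.57, adjusted p = 0.369 with an estimated correlation).

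Single arrays stood apart from the other 3 of their group by Dixon's ratio in 10 of 169 gene values and in 1 of 20 array measures, where chance picks out about 1 in 20 groups. LCT under 5-ASA was 3.027 on replicate 4 against 2.227 to 2.274 on the others, and under GED 30 mM 2.529 on replicate 2 against 2.049 to 2.118. MBL2 was 1.174 on GED 30 mM replicate 3 (others 1.402 to 1.433) and 1.597 on pioglitazone replicate 3 (others 1.403 to 1.422). FABP1 was 0.1284 on 5-ASA replicate 2 (others 0.3705 to 0.4018), and SLC30A1 1.148 on the same array (others 1.263 to 1.281). Under GED 1 mM, ABCC3 was 0.4659 on replicate 4 (others 0.3372 to 0.35), ASCL2 -0.4013 on replicate 1 (others -0.2501 to -0.2305), SLC12A2 -0.4245 on replicate 3 (others -0.3081 to -0.2951) and PDK4 -0.01565 on replicate 3 (others 0.1417 to 0.1629). PDK4 was not well above background in either channel there, so its values are near the floor. The median Cy5 signal of GED 1 mM replicate 3 was 178.8 (others 187.8 to 189.2).

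Probes without a gene symbol also changed: of 5779 measured, 80 were called for GED 1 mM (0 of them 2-fold), 2464 for GED 30 mM (55 of them 2-fold), 3726 for 5-ASA (219) and 938 for pioglitazone (4).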

How the results depend on the processing

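Chosen after results were seen were the tests with the background kept, with slide as a fixed block, with a dye effect per slide and with control wells given a spread. So were the alternatives (not the counts themselves) for the pairs with pioglitazone and for 5-ASA minus GED 1 mM, and leaving out arrays for the lists, and the other tests were chosen before.

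The GED 1 mM count of 1891 moved most. It was 1091 with median centring (93.6% of calls higher, against 59.5%), 555 with no dye term, 2892 with its own arrays alone, 3229 with slide as a random block, 3175 with array weights, 596 (without replicate 1) to 1804 (without replicate 3) when 1 array was left out, 298 with the local background kept as scanned and 95 with control wells given the spread of the arrays. Without a dye term the dye effect goes into the error by construction. With the background kept the spreads of the 4 GED 1 mM arrays hardly moved (0.137 to 0.175 in both settings). That of 5-ASA replicate 1 went from 0.525 to 0.215 and that of GED 30 mM replicate 1 from 0.320 to 0.204. All treatments share 1 error estimate per gene, so the drop to 298 came without a change in the spread of the GED 1 mM arrays. The causes of the other moves were not tested. The pioglitazone count of 5512 was 3505 with no dye term, 2900 with the background kept and 3122 with control wells given a spread.

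The 442 genes shared by all 4 treatments were 194 with median centring, 182 with no dye term, 88 with the background kept, 45 with control wells given a spread and 223 to 505 when 1 array was left out. GED 30 mM minus GED 1 mM (7297) was 3829 with the background kept and 3556 with control wells given a spread, GED 30 mM minus pioglitazone (8295) was 5065 and 5241, and GED 1 mM minus pioglitazone (3417) was 904 and 433, and 1334 with no dye term.

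With every probe on its own the counts are of 28462 probes by construction: 16083 for GED 30 mM, 21210 for 5-ASA, 8357 for pioglitazone, 16615 for GED 30 mM minus 5-ASA, 12072 for GED 30 mM minus GED 1 mM, 13801 for GED 30 mM minus pioglitazone, 19408 for 5-ASA minus pioglitazone and 18940 for 5-ASA minus GED 1 mM. Of 42 list calls 11 held with an estimated correlation.

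A replicate block gave 1675 genes for GED 1 mM, 9122 for GED 30 mM, 11425 for 5-ASA and 5318 for pioglitazone. Replicate numbers did not pair samples across treatments: 7 of 24 pairs correlated above 0.1 (-0.283 to 0.32).

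Of 4609 values of named genes, 4518 were called, or not called, as in the main fit, 74 became weaker, 13 stronger and 4 reversed. These values repeat 212 results over the alternatives, and 177 of the 212 stayed the same throughout. With the stricter filter the probe that rose drops out, and TESMIN was -0.05689 under 5-ASA and 0.3749 in the 30 mM difference. SLC12A2, GED 30 mM minus 5-ASA 30 mM, was -0.2815 as the mean over probes and -0.04393 with the background kept.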

Other observations

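In this part the tests of less mitochondrial RNA of every kind, of single probes and of dye effects outside the 2-fold genes were chosen after the result was seen, and the other tests before.

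The genes of this paragraph were picked after their values were seen. HSPA5, the main chaperone of the endoplasmic reticulum, fell by 1.18 under GED 30 mM and by 1.87 under 5-ASA, and PDIA4, a folding enzyme, fell by 0.50 and by 1.26, while ATF3 rose by 0.77 and by 3.19. HERPUD1, which serves the removal of misfolded proteins, rose in all 4 treatments, by 0.54 (GED 1 mM), 0.92 (GED 30 mM), 0.17 (5-ASA) and 1.14 (pioglitazone). The ATF4 and unfolded protein list as a whole was not called (GED 30 mM 14 of 27 higher and 10 lower, 15 and 10 adjusted over the list alone, camera adjusted p = 0.283; 5-ASA 11 higher and 13 lower, camera adjusted p = 0.884), nor in the difference between them (camera adjusted p = 0.633).

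Lists without a call in any treatment held large single changes, and the genes named here were picked after their values were seen. The p53 targets had 3 of 15 higher and 7 lower under GED 30 mM (4 and 8 adjusted over the list alone, camera adjusted p = 0.398), with the kinase PLK3 at -1.39 and the cytokine GDF15 at -1.13, and TP53INP1 rose by 1.46 under 5-ASA. The adhesion molecule ICAM1 fell by 1.05 under GED 30 mM and by 0.85 under 5-ASA, in an inflammatory list with 6 of 20 higher and 8 lower under GED 30 mM (camera adjusted p = 0.489). SNAI1, a repressor of epithelial genes, fell by 0.54 under GED 30 mM and rose by 1.02 under 5-ASA, with 3 of 13 mesenchymal transition genes higher and 7 lower under GED 30 mM (camera adjusted p = 0.271). Enteroendocrine and Paneth markers had 1 of 9 higher and 3 lower under GED 30 mM (camera adjusted p = 0.271), and stromal and immune markers 1 of 9 higher and 5 lower (camera adjusted p = 0.374). In GED 1 mM the median, mean and test differed in sign for the cholesterol, ATF4, glycolysis, goblet, stem cell and stromal lists, in GED 30 mM for the PXR list, and in pioglitazone for the AhR, PXR, ATF4, p53 and enteroendocrine lists, and none of these was called.

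The mitochondrial transcripts under 5-ASA fell in part: 6 of 10 genes with a probe on the mitochondrial chromosome were far lower (median -2.10) while ND5 rose. The 155 nuclear genes of matched intensity had a median of -0.0116 (SE 0.0438). This cannot decide whether normalization of bright probes plays a part, because the loess step by itself sets the median ratio at each intensity near 0. Less mitochondrial RNA of every kind does not account for the pattern, since ND5 had 1.40 (SE 0.121). The behaviour of single probes does not for ND3 and CYTB, whose 2 further probes both fell, and cannot be tested for the other fallen genes, which have 0 further probes. The level of ND6, read from the other strand, fell as well (-1.80). COX3 kept a range of -3.92 to -3.74 over 22 settings, median centring without loess among them, and what lowers these transcripts stays open.

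The ratios of GED 1 mM ran parallel to those of pioglitazone, at 0.389 of their size over 75 genes 2-fold changed by pioglitazone. For these 75 genes dye effects left in both groups do not account for it, since arrays of opposite dye correlated at 0.731 and 0.78 (0.785 and 0.796 for the same dye). A dye effect that is the same on all arrays of a group cancels in means over 2 arrays per dye, so by design it does not account for the parallel in the other genes. Over the other genes r was 0.448, and 0.454 given the dye effect of the 30 mM arrays. That value decides nothing more, since the ratios hardly followed this dye effect (r = 0.0843 for GED 1 mM and -0.0411 for pioglitazone). A dye effect that varies between arrays of a group was not tested over the other genes. The first test over those genes, arrays of opposite dye at 0.0112 and 0.0444, decides nothing because a shared dye effect lowers it by itself, and genes are not independent replicates. Chance values of the pioglitazone pool do not account for the parallel either (r = 0.599 across all genes against the other pool), and the parallel may reflect a shared PPAR response of lower strength, which the lack of GED 1 mM wells on the other slides leaves open.

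Splits of the 8 arrays of a pair into other groups of 4 gave these results. For genes differing between GED 30 mM and 5-ASA, 1 of 35 splits (the real one) reached 9408, and the highest other gave 1. In the same way 1 of 35 reached 7297 (GED 30 mM minus GED 1 mM, highest other 0), 8295 (GED 30 mM minus pioglitazone, 0), 10694 (5-ASA minus pioglitazone, 0), 3417 (GED 1 mM minus pioglitazone, 17) and 10405 (5-ASA minus GED 1 mM, 0). The other splits mix both treatments, which puts their difference into the error, so low counts there are built in. The real split would lead for anything that separates the groups. In every pair but GED 30 mM and 5-ASA the control pools differ too, and in pairs with GED 1 mM so do slide and scan day. These splits cannot tell treatment from those. For the 7 gene lists differing between GED 30 mM and 5-ASA, 12 of 35 splits gave at least as many and the highest other gave 9. Splits with unequal shares of the treatments on each side keep part of their difference, which can give list calls by itself. These splits are therefore no measure of chance, and they cannot decide whether chance gives that count of lists.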
